A study of Mus musculus with 8 samples.

How the data were processed

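RNA was extracted from sorted cells with a kit for small samples, labelled with biotin and hybridised by a standard Affymetrix protocol, per the labels' protocols. The study covers 8 arrays, 3 KO and 5 WT, with groups taken from the genotype label and replicate numbers from the sample titles. The authors deposited 1 table of log2 values, 28846 rows by 8 arrays. The software, background correction, normalization between arrays and genome build behind it are not given in the sources used here. The log base was taken from the range of the values, 1.89 to 18.6, and no label states it, so folds rest on that reading. The array medians differed, from 5.26 to 5.51. Scanner files were not used here.

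The table held 22206 transcript rows and 6640 control rows, among them 1324 positive controls, 5222 negative controls and 63 ERCC rows. Gene names came from a table pairing row identifiers with the platform annotation. The submitters' design text names an Affymetrix mouse transcriptome array, and the annotation, whose identifiers match the rows, appears to belong to another Affymetrix mouse array, so which of them was used is open. With it, 19572 transcript rows had 1 symbol, 0 had several and 2634 had none. All 19572 had a gene identifier found in a RefSeq gene table of assembly GRCm38.p6, which was used for names only. The build behind the deposited table is not named, so no coordinates are given. The symbols covered 19505 genes.

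A row was tested if it had 1 symbol and lay above the median of all rows of the array on at least 3 arrays. For each symbol the row with the highest mean was kept, which left 9920 genes, 9802 of them protein coding. The filter removes genes silent in both groups, and a gene near it can be missed. KO was compared with WT by limma (version 3.58.1, R 4.3.3, lmFit and eBayes, two-sided) on the deposited log2 values with no further normalization, and p-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. Single genes of interest also had an exact two-sided permutation test over 56 splits, whose smallest p is 0.0179. Before the data were examined, 37 gene lists were fixed from textbook knowledge of the pathways, the leukaemia and the cell types that the sort could hold. The 29 lists with at least 5 tested members entered limma's camera with a preset correlation of 0.01, beside camera with an estimated correlation and fry. Fry asks whether the genes of a list move one way on balance, or in either direction in its mixed form, and does not compare the list with other genes. With an estimated correlation 0 lists passed, and fry passed 0 in either form, with smallest adjusted p of 0.970 and 0.876.

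The genes named in the text follow a rule also fixed before the data were examined. It takes 5 PI3K genes, the 12 largest changes in each direction among genes that passed without overlap of the groups or, where fewer than 6 passed, the 6 with the smallest unadjusted p, up to 4 members of each list with the smallest unadjusted p, and all sex-linked genes in the table. The lists whose genes are named, and the 13 lists followed across alternatives, were picked after values were seen. In each list named gene by gene, all members that the rule takes are given. Prg3 and Clec1b fall outside the rule and were chosen after their values were seen. Xist and Ddx3y are not named in the table.

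The scripts were tested on simulated data. In 20 runs on 9920 genes, 200 genes were changed, with the spread of the real arrays and the real deviations of WT array 3 kept. Of genes changed by 2-fold, the KO against WT test recovered 8.3% with all 8 arrays and 34.6% without WT array 3, and of genes changed by 4-fold 70.4% and 92.8%. False calls averaged 0.8 and 7.25 a run. Changes of 2-fold were therefore mostly below what these arrays can call. A shift of 0.5 planted in a list was called by camera in 18 of 20 separate runs. Those runs had no correlation between genes and did not keep the deviations of WT array 3. Their recovery therefore does not carry over to the real arrays.

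The alternatives fixed before the data were examined were no filter and a stricter filter on dim rows (60th percentile on 5 arrays), quantile normalization, median centring, a floor at the 25th percentile, eBayes with trend and robust, array weights, the replicate number as a block, leaving out each array, all transcript rows, the row of largest variance, a Welch statistic, other thresholds of fold change, and the other set tests. A further 5, which leave out arrays that stand apart, were chosen after seeing the data. No pair of arrays was a duplicate, with a smallest root mean square difference of 0.684. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.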

Results

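Gene expression was measured by microarray in leukaemia stem cells of mice. The cells were GFP-positive granulocyte-macrophage progenitors (GMPs), sorted from the bone marrow of transplant recipients whose leukaemia was driven by MLL-AF9, a fusion oncogene that turns myeloid progenitors into self-renewing leukaemia cells. The samples were 3 arrays from cells lacking Pik3ca (KO) and 5 arrays from wild-type cells (WT). Pik3ca encodes the p110-alpha catalytic subunit of class I phosphoinositide 3-kinase (PI3K), which passes growth factor signals to AKT. The comparison asked which transcripts differed between leukaemia stem cells with and without this subunit. All values are the deposited log2 values, which ranged from 1.89 to 18.6 over 28846 rows, with array medians between 5.26 and 5.51. The number of arrays limited the precision, and the labels do not say whether the arrays of a group came from separate mice, so p-values measure the spread between these samples only.

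The targeted gene was read first in every array. Pik3ca was 8.73, 9.31 and 9.40 in the KO arrays and 9.48, 9.57, 8.41, 9.51 and 9.58 in WT arrays 1 to 5, which gives 9.15 ± 0.36 (SD, n = 3) in KO and 9.31 ± 0.51 (SD, n = 5) in WT. The difference of -0.16 was within the spread of the arrays, with an exact two-sided permutation p of 0.661 over 56 splits. WT array 3 held the lowest Pik3ca value of the 8. Without that array the difference was -0.39, with all 3 KO arrays below the other 4 WT arrays, and the exact permutation p was 0.0286, the smallest that 35 splits can give. In limma the unadjusted p was 0.622 with all arrays and 0.0823 without WT array 3, with adjusted p of 0.998 and 0.989. Without KO array 1 the difference was 0.04, in the other direction. The labels do not name the deleted part of the gene, and probes outside it would not report its loss, so Pik3ca did not check the genotype labels. Among 4 other class I PI3K genes, Pik3cb, which encodes the catalytic subunit p110-beta, was 13.99 ± 0.08 (SD, n = 3) in KO and 13.69 ± 0.80 (SD, n = 5) in WT. Pik3cg, encoding p110-gamma, was 11.03 ± 0.53 (SD, n = 3) in KO and 9.99 ± 2.22 (SD, n = 5) in WT, and Pik3r1, encoding the p85-alpha regulatory subunit, was 12.58 ± 0.04 (SD, n = 3) and 11.86 ± 1.36 (SD, n = 5). Pik3cd, encoding p110-delta, was 8.13 ± 0.89 (SD, n = 3) and 8.16 ± 1.04 (SD, n = 5), a difference of -0.03 that turned to 0.01 after centring each array on its median. None of these 4 differed in the exact permutation test, with p of 0.679 for Pik3cb, 0.643 for Pik3cg, 0.554 for Pik3r1 and 0.964 for Pik3cd. Without WT array 3, the differences were -0.03 for Pik3cb, 0.08 for Pik3cg, 0.13 for Pik3r1 and -0.48 for Pik3cd.

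WT array 3 stood apart from the others. Its mean correlation with the other arrays, across genes, was 0.921, against 0.968 to 0.972 for the other 7, and the first principal component, which held 50.8% of the variance, set it against all the rest. Positive and negative control rows were least well separated on it, with an area under the curve of 0.858 against 0.894 to 0.934 elsewhere, and its hybridization spikes had the highest median, 12.5 against 11.2 to 11.6. On this array 732 of the 9920 tested genes lay over 2 log2 units below the mean of the other WT arrays and 135 lay as far above it. Each comparison was therefore also made without it.

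**Figure D1:**
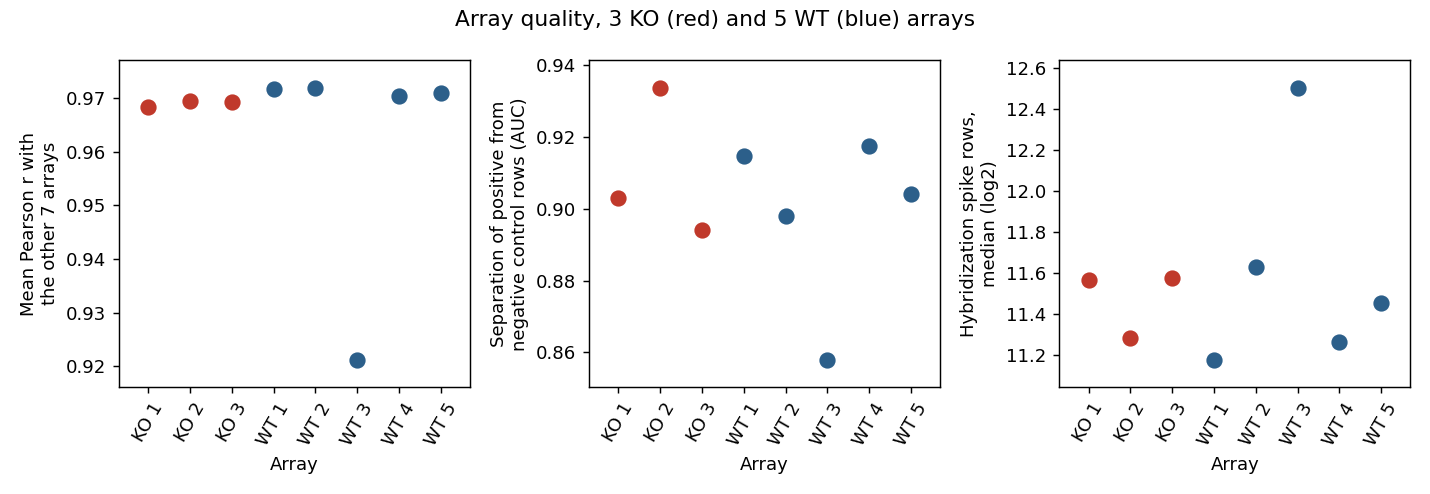
Each point is 1 array, KO in red and WT in blue: mean Pearson correlation with the other 7 arrays across the tested genes, area under the curve separating positive from negative control rows, and median log2 value of the hybridization spike rows. WT array 3 is the lowest in the correlation and control row panels and the highest in the spike panel, at 0.921, 0.858 and 12.5. Among the WT arrays, the outlier search described below flagged its correlation and not the other measures.

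No gene passed the test between KO and WT. Of 9920 genes tested with limma, 0 were higher and 0 were lower in KO at an adjusted p under 0.05, and the smallest adjusted p was 0.998. At an unadjusted p under 0.05 there were 282 genes, 146 higher and 136 lower, where 496 would be expected by chance. All KO arrays lay outside the range of the WT arrays for 307 genes, or 3.09%, against 3.57% by chance. Without WT array 3, limma again called 0 genes, the smallest adjusted p was 0.465, and 464 genes were at an unadjusted p under 0.05, with 220 higher and 244 lower. The median standard error of a difference was 0.311 with all arrays and 0.240 without that array.

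The genes with the smallest unadjusted p in each direction are given as values that did not pass. Lower in KO were Il6st, which encodes gp130, the shared signalling receptor of the interleukin-6 family, at 6.31 ± 0.44 (SD, n = 3) against 8.37 ± 0.54 (SD, n = 5), and Bcl2, encoding the anti-apoptotic protein, at 7.94 ± 0.49 (SD, n = 3) against 9.48 ± 0.36 (SD, n = 5). The log2 difference was -2.06 with a standard error of 0.35 for Il6st and -1.54 with a standard error of 0.29 for Bcl2. Snx7, a sorting nexin, differed by -1.90, Orai3, a subunit of store-operated calcium channels, by -1.13, Tet1, an enzyme that oxidises 5-methylcytosine, by -1.45, and the kinase gene Mast3 by -0.85. Higher in KO were Xpnpep3, an aminopeptidase gene, at 9.77 ± 0.05 (SD, n = 3) against 8.52 ± 0.37 (SD, n = 5), Homer1, encoding a scaffold protein, with a difference of 1.56, and Slfn9, of the Schlafen family, with 1.64. Tor3a differed by 1.04, Tie1, an endothelial receptor gene, by 0.97 and Btla, an inhibitory lymphocyte receptor gene, by 0.90. Tie1 was above the median row of the array on 1 of the 5 WT arrays and Btla on 0. In all 12 genes the KO and WT arrays did not overlap, which choosing by p favours, and without WT array 3 the differences were -1.87 for Il6st, -1.40 for Bcl2 and 1.38 for Xpnpep3.

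**Figure D2:**
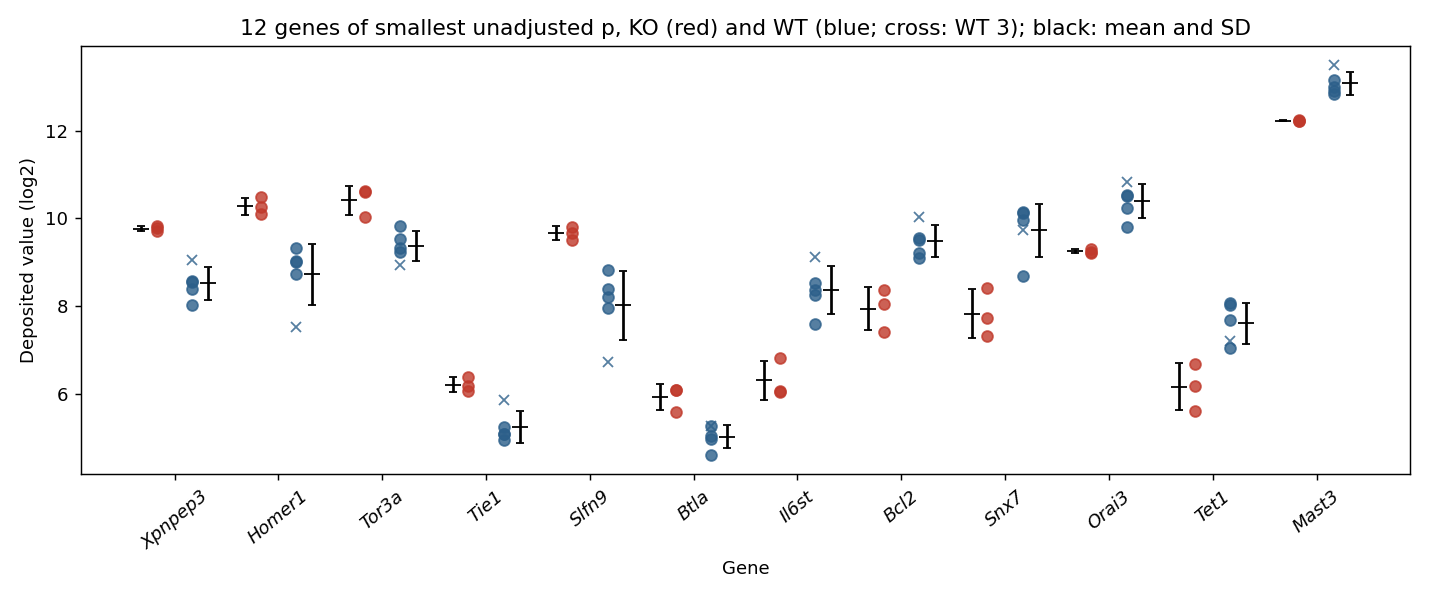
Deposited log2 values of the 12 genes with the smallest unadjusted p, 6 higher and 6 lower in KO, for 3 KO arrays (red) and 5 WT arrays (blue, with WT array 3 as a cross). Black marks are the mean and SD of each group. KO and WT arrays do not overlap in any of the 12, and no gene passed the adjusted test.

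Genes of the G1/S transition, which license and start DNA replication, had a median difference of 0.28 as a list, with quartiles of 0.23 and 0.36. Of its 19 tested members, 18 had a difference above 0 and 0 passed the test over all genes. Averaged per array, the list was 0.31 higher in KO, which was within the spread of the arrays, with an exact two-sided permutation p of 0.196. Gins1, a subunit of the replicative helicase, was 12.7 ± 0.10 (SD, n = 3) in KO and 11.7 ± 0.53 (SD, n = 5) in WT. Cdc6, a licensing factor, differed by 0.51, and by 0.24 without KO array 2, Ccne1, encoding cyclin E1, by 0.31, and by 0.21 without WT array 5, and Mcm5, a helicase subunit, by 0.33, and by 0.15 without WT array 3. In the set test with a preset correlation (limma camera) the list had an adjusted p of 0.0152, the only 1 of 29 lists under 0.05. The adjusted p was 0.864 with an estimated correlation and the smallest in fry over the lists was 0.970. WT array 3 was low in this list, with a median shift of -0.63 against the other WT arrays. KO arrays 1 to 3 were at 0.35, 0.48 and 0.02 against the mean of all WT arrays. WT arrays 1, 2, 4 and 5, each against the other WT arrays, were at 0.30, 0.30, 0.07 and -0.01. The references for these KO and WT shifts hold WT array 3. The camera adjusted p was 0.0734 without WT array 3, where the median difference was 0.15, and it was 0.113 without KO array 1, 0.277 without KO array 2 and 0.0662 without WT array 5. Adjusted over the list alone, 0 members passed with all arrays, and 1, Gins1, without WT array 3. Genes of the G2/M phase had a median difference of 0.13 over 19 members, with a camera adjusted p of 0.468. Without WT array 3, whose median shift in this list was -0.51, the median was 0.06.

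The lists closest to the deleted kinase showed no called shift. Of the class I PI3K subunits and lipid phosphatases, 12 were tested and 0 passed, 5 with a difference above 0 and 7 below, and the median of -0.02 turned to 0.01 with quantile normalization and to 0.02 with median centring. It was -0.13 without WT array 3, 0.16 without KO array 3 and 0.13 without WT array 4. Among its members, the regulatory subunit genes Pik3r3 and Pik3r5 differed by 0.41 and -0.44, and by 0.25 without WT array 4 and -0.13 without WT array 3. Pik3r3 was dim, above the median row of the array on 2 KO arrays and 1 WT array. Of 20 AKT and mTOR components, 0 passed, with a median of -0.04 that turned to 0.01 with median centring. FoxO targets, genes held down by AKT through FoxO transcription factors, had a median of -0.16 over 14 members, with 0 passing and a camera adjusted p of 0.414. The FoxO targets Ccng2 and Irs2 differed by -0.59 and -0.36 and Cited2 by -0.29, while Sesn1, a stress-induced gene of the sestrin family, differed by 1.03. Cited2 was at -0.18 and Sesn1 at 0.51 without WT array 3. For this list the camera adjusted p was 0.0135 without the filter on dim rows, and 0.730 there with an estimated correlation. The median was 0.13 with a stricter filter and 0.08 without KO array 3.

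Metabolic lists were mixed. Of 15 tested cholesterol synthesis genes and SREBP2 targets, 10 were above 0 and 0 passed, with a median of 0.13 that was -0.01 without KO array 2. Hmgcs1, an early enzyme of the mevalonate pathway, differed by 1.32, Nsdhl by 1.13, Lss by 0.99 and Fdps by -0.33. Without KO array 1, Lss was at 0.64 and Fdps at -0.16. Of 17 glycolysis genes, 0 passed, with a median of 0.15, where Hk2, a hexokinase, differed by -0.75, Pfkl and Pfkp, phosphofructokinases, by 1.18 and -0.64, and Pdk1, a kinase that restrains pyruvate dehydrogenase, by 1.54. Without WT array 3, Pfkl differed by 0.80, Pfkp by -0.99 and Pdk1 by 1.02, and without KO array 1 Pfkp differed by -0.40. WT array 3 had a median shift of -1.26 in the glycolysis list. Without it the median was 0.03 and 1 member, Hk2, passed when adjusted over the list alone. Asns, the asparagine synthetase gene in the ATF4 list, differed by 0.70, Shmt2 by -0.41, Hspa5 by 0.58 and Herpud1 by 0.37, and 0 of that list's 14 members passed. Hspa5 and Herpud1 were at 0.19 and 0.13 without WT array 3 and Shmt2 at -0.26 without KO array 3. Of 9 tested NF-kB and inflammatory genes, 0 passed, with a median of -0.20 that was 0.08 without KO array 1 and 0.03 without WT array 1. Ccl3, a chemokine gene, differed by -1.11, Nfkb2 by -0.75, Tnf by -0.45 and Icam1 by 0.32. Ccl3 was dim, at 5.03 to 6.77 in WT against array medians of 5.26 to 5.51, and its mean in KO was lower still. Tnf was at -0.28 without KO array 2 and Icam1 at 0.15 without WT array 3. Icam1 was dim too, at 4.33 to 5.57 in WT, as were Hmgcs1 at 5.47 to 7.11 and Pdk1 at 3.85 to 7.14 in WT.

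Lists of the leukaemia programme and of the myeloid lineage did not pass the set test. In the MLL fusion self-renewal programme, 14 genes were tested and 0 passed over all genes. The median of 0.13 was -0.01 without WT array 3. Adjusted over the list alone, 1 member passed, Bcl2, and the other 3 members taken by the rule were Pbx3, a cofactor of HOX proteins, at -1.93, Eya1 at -1.71 and Hoxa5 at 0.66. Pbx3 was 11.7 in WT array 4 and between 6.66 and 8.38 in the other WT arrays, and differed by -1.14 without it, and Eya1 differed by -0.34 without KO array 1. Adjusted over the list alone, Bcl2 also passed in the BCL2 family (1 of 9), Tet1 among chromatin regulators of MLL leukaemia (1 of 19), and Ms4a6c among monocyte and macrophage markers (1 of 14). This adjustment does not correct for the number of lists, 37, of which 4 held a passing member. In the BCL2 family, Bcl2l11 differed by -0.42, Bid by 0.32 and Bak1 by 0.34, and among the chromatin regulators Cbx7 by -0.74, Kdm4c by 0.82 and Kdm6b by -0.42. Cbx7 was dim, at 4.99 to 6.52 in WT against array medians of 5.26 to 5.51, and its mean in KO was lower still. Leaving out KO array 2 brought Bcl2l11 to -0.13 and Bak1 to 0.01, and leaving out WT array 3 brought Bid to 0.06, Kdm4c to 0.31 and Kdm6b to -0.23. Values also moved away from 0: without KO array 3, Bak1 differed by 0.71 and Eya1 by -2.83. Ms4a6c differed by -1.14 and Irf8, a transcription factor of the monocyte and dendritic cell lineages, by -0.97, and by -0.50 without KO array 1. Vcam1, an adhesion molecule gene, differed by 1.52 and Cx3cr1 by -0.50, and by -0.34 without KO array 3. The monocyte list had a median of -0.09 that was 0.08 without KO array 1, -0.48 without KO array 2, 0.19 without WT array 1 and -0.30 with array weights. Genes of primary granules and GMPs, the sorted population, had a median of 0.06 over 16 members, 12 of them above 0, and of -0.01 without WT array 3, with 7 above 0. In this list were Nkg7 at -0.74, Kit at -0.30, Calr at 0.56 and Fcgr3 at 0.27. Nkg7 was at -0.42 without KO array 1 and Calr at 0.27 without WT array 3. In the stem cell list Cd34 differed by -2.0, Gata2 by -0.87, Mllt3 by 0.35 and Mecom by 0.42. Gata2 was at -0.52 and Mecom at -0.12 without WT array 3, and Mllt3 at 0.15 without KO array 2. In the dendritic cell list Tcf4 differed by -1.10, while Ciita at -0.11 and H2-Aa at 0.0017 lay near 0 and turned in sign with 1 array left out. Among cytokine receptors Il3ra, the interleukin-3 receptor alpha gene, differed by -0.93, Il6ra by -0.56 and Igf1r by 0.38. Il6ra was at -0.22 without KO array 2 and -1.09 without KO array 1, and Igf1r at 0.04 without WT array 3. No gene of these lists passed the test over all genes.

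Markers of other cell types that the sort could hold varied between arrays. Megakaryocyte and platelet markers had a median difference of -0.44, with 8 of 8 tested members below 0, 0 passing and a camera adjusted p of 0.121. With an estimated correlation, the camera adjusted p was 0.864. WT array 1 carried a median shift of 2.48 in this list, and without it the median difference was 0.08. The list passed camera without WT array 2, 4 or 5, with adjusted p of 0.0305, 0.0406 and 0.0481, and with an estimated correlation these were 0.830, 0.911 and 0.978. Itga2b, a platelet integrin gene, differed by -1.15, Pf4 by -1.41, Treml1 by -0.51 and Gp9 by -0.36. Without WT array 1, Itga2b differed by -0.66, Pf4 by -0.22 and Treml1 by 0.07, and without WT array 3 Gp9 differed by -0.17. Mast cell, basophil and eosinophil markers had a median of -0.55 over 8 members, with 7 below 0 and a camera adjusted p of 0.121, and 0.864 with an estimated correlation. The median was -0.17 both with no filter and with the stricter filter on dim rows, and -0.34 without WT array 4. Cpa3, a mast cell protease gene, differed by -1.04, and by -0.69 without KO array 3, Prg2, an eosinophil granule gene, by -2.19, and by -1.40 without WT array 4, and Hdc, encoding histidine decarboxylase, by 0.76, and by 0.10 without KO array 1. Few B cell, T and NK cell, dendritic cell, erythroid or stromal markers were bright enough to test: 4, 3, 3, 3 and 3 members, of which 0 passed. The Y-linked genes Uty and Kdm5d were lowest in WT array 3, at 4.004 and 2.998, and low in KO array 1, at 4.54 and 3.17. In WT array 4 Kdm5d was 3.93 and Uty 7.30. Eif2s3y lay between 2.64 and 3.93 in all arrays.

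**Figure D3:**
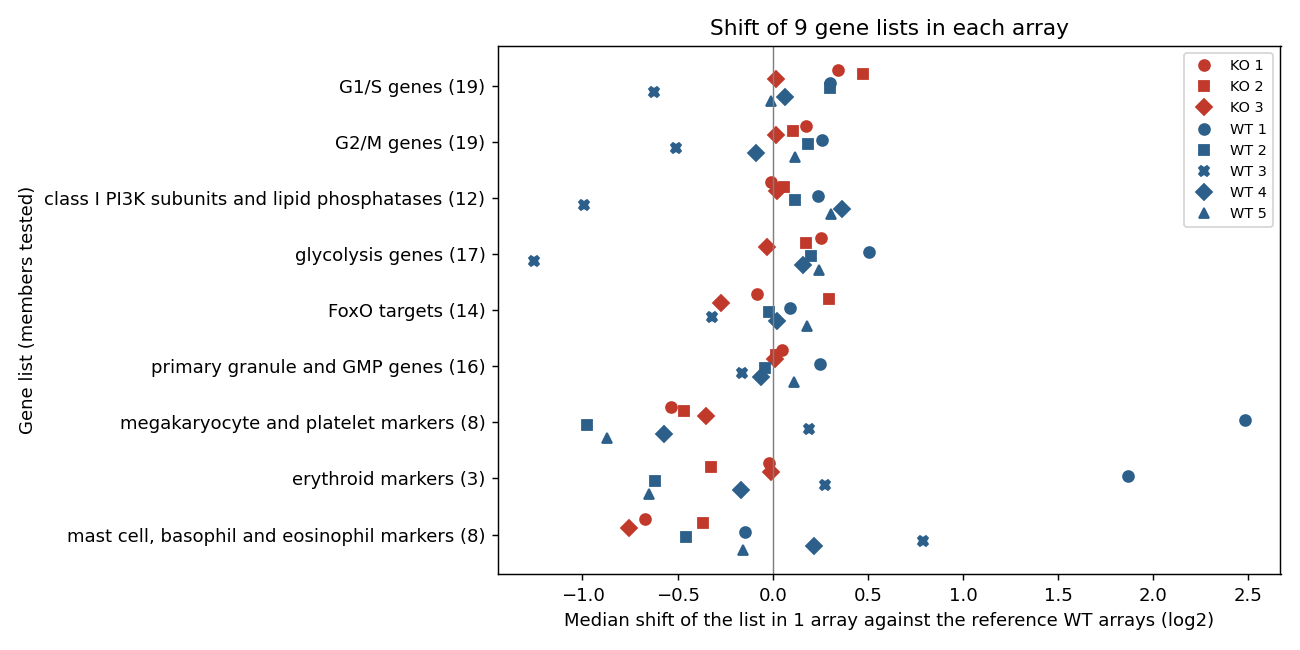
Median shift (log2) of 9 gene lists in each array, KO in red and WT in blue. A KO array is set against the mean of all WT arrays and a WT array against the mean of the other WT arrays. WT array 3 lies lowest in the G1/S, G2/M, PI3K and glycolysis lists, at -0.63, -0.51, -0.99 and -1.26, and WT array 1 lies at 2.48 in the platelet list.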

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

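The tests on WT array 3, on WT array 1, on the share of WT array 3 or of 1 KO array in the G1/S shift, and the split count for genes passing the adjusted test were chosen after the results they measure had been seen. The other split counts were set beforehand.

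In the 5 WT arrays, 87 values of the named genes and array measures were searched for an array far from the rest, by the gap to its nearest neighbour over the range of the group, and 17 were found. Chance gives about 1 in 20. WT array 3 accounted for Pik3ca at 8.41, Pik3cg at 6.15, Pik3r1 at 9.48, Pfkl at 5.65, Pfkp at 10.1, Calr at 12.2, Hdc at 7.17, Hspa5 at 11.05, Herpud1 at 12.1, Kdm4c at 5.79, Igf1r at 9.72, Uty at 4.004, an ERCC row median of 6.32 and a mean correlation with the other arrays of 0.921. Snx7 was low in WT array 1, at 8.69, where Treml1 was high, at 8.45, and Ccl3 was low in WT array 2, at 5.03. The separation of control rows and the hybridization spikes of WT array 3 were not flagged, with ratios of 0.674 and 0.660 against a bound of 0.71. Over all tested genes, the same search found WT array 3 far from the rest in 1440 genes, or 14.5%, against 45 to 65 genes in each other WT array.

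WT array 3 stands apart from KO and WT arrays alike. As the source of the genes low on it, dilution by cells that lack the genes of the GMP list was argued against. The median shift of that list was -0.16 with quartiles of -0.30 and -0.03, and 2 of its 16 members were lower by over 1 log2 unit. Of all tested genes, 7.38% lay over 2 log2 units below the other WT arrays. Cells that share genes of the GMP list would not lower them, so dilution by such cells was not decided. For the genes high on WT array 3, other cells in the sample cannot be told apart from a poor array. Of 9 marker lists of other cell types, 7 had a median above 0, among them T and NK cells at 1.31, mast cells, basophils and eosinophils at 0.79 and B cells at 0.69, while monocyte markers were at -0.45 and stromal markers at -0.53. Most of these lists held 8 or fewer tested members. A wrong genotype label alone would not set the array apart from both groups: its mean correlation with the KO arrays was 0.920, against 0.974 for the lowest pair among the other arrays. Whether the label is right stays open, since a poor array would hide it. Its Pik3ca was the lowest of the 8, which does not bear on the label. Its Pik3cb, Pik3cd, Pik3cg and Pik3r1 were also the lowest of the 8, at 12.4, 6.40, 6.15 and 9.48. Weak or degraded labelled RNA may account for it, with the lowest separation of control rows, 0.858, and the highest hybridization spikes, 12.5. The outlier search flagged neither of these values. No biological explanation was tested, and a real difference between leukaemias stays open.

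The higher G1/S list in KO could not be separated from chance. Its camera p was 0.000525, and 7 of the 56 splits of the arrays gave one as small, with 1.10e-06 as the smallest of the others. At least as many lists as the 1 of the real comparison passed in 40 of the 56 splits, with 6 as the highest of the others. With 1 KO array left out the lowest median was 0.18, and the call was lost without KO array 1 or 2. These fits all hold WT array 3, whose shift in this list was -0.63, so they cannot decide on an effect of 1 KO array alone. Without KO array 1 and WT array 3 the median was 0.11. An effect of WT array 3 alone cannot be told apart from a difference between the groups: without it the median was 0.15, 17 of 19 members were above 0, and the mean per array differed by 0.18 with an exact permutation p of 0.286. A first criterion, at least 15 of 19 members above 0 with a preset camera p under 0.05, was met, with a camera p of 0.00434, and excluded this explanation. It was replaced by the exact test after those values had been seen. An effect of the genotype stays open and untested beyond this.

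The platelet genes in WT array 1 may come from platelet or megakaryocyte RNA in that sample. Of 8 tested markers, 7 were highest there, while 9.77% of all tested genes were, and the GFP-positive GMP gate would be expected to remove such cells. Pf4 was 12.4 against a median of 6.30 in the others, Clec1b, chosen after its values were seen, was 11.5 against 7.06, and Itga2b was 9.55 against 6.62. Erythroid markers were also high in this array, with a median shift of 1.87 over 3 tested members and 2 of them, Alas2 and Slc4a1, highest there, so the sample may hold RNA of more than platelets. A shift of the whole array was argued against by the median shift of all tested genes, 0.0785. A megakaryocytic or erythroid programme of that leukaemia was not tested.

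The absence of called genes in KO against WT was matched in 56 of the 56 splits, as any count of 0 must be, and the highest of the others was 0. At an unadjusted p under 0.05, 39 of the 56 splits gave at least the 282 genes of the real comparison, so chance was not excluded for this count, and the highest of the others was 893. The 21 splits with WT array 3 in the group of 3 gave a median of 551 genes and the 35 others a median of 282, so the larger counts follow that array.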

How the results depend on the processing

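The 5 settings that leave out 2 arrays, or WT array 3 with another model or normalization, were chosen after seeing the data. Of 101 values tried, 66 kept their direction and side of the threshold under every alternative run. For single genes this says nothing about stability, since no gene came near the threshold and choosing 12 genes by the smallest p favours groups that do not overlap. Of 65 other genes named from the lists, the Y-linked ones included, 46 moved by over 1.5 times, or turned, with 1 array left out, and 8 of them turned in sign. The count of genes passing was 0 under every alternative except an unadjusted p under 0.05 with at least a 2-fold change, which gave 101 genes, 43 higher and 58 lower in KO. Unless a construction is named, the cause of a change was not tested. The median standard error was 0.311 in the fit that holds WT array 3, the array with the lowest separation of control rows, 0.858, and 0.240 without it.

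The number of genes at an unadjusted p under 0.05, 282, was 592 with no filter on dim rows, where 19505 genes were tested, and 446 with array weights, which gave WT array 3 a weight of 0.149. It ran from 220 to 464 with 1 array left out, the highest without WT array 3. With WT array 3 left out it was 432 with trend and robust eBayes and 482 with quantile normalization, 426 without WT arrays 1 and 3, 438 without WT arrays 3 and 4, and 486 without KO array 1 and WT array 3. The number of lists passing camera, 1, was 2 with no filter, 0 with array weights, 0 with an estimated correlation, 0 with fry in both forms, and between 0 and 2 with 1 array left out. Without WT array 3 it was 2 with trend and robust eBayes and 0 with quantile normalization.

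The G1/S list kept a median above 0 under every alternative run. With the preset correlation it passed camera in 13 of 23 settings, the main one included. These include WT array 3 left out with trend and robust eBayes (adjusted p 0.0166) and WT arrays 1 and 3 left out (0.0358). Its call was lost with array weights (median 0.18, adjusted p 0.0529), with an estimated correlation (0.28, 0.864), without WT array 3 under quantile normalization (0.14, 0.228), without WT arrays 3 and 4 (0.10, 0.207) and without KO array 1 and WT array 3 (0.11, 0.289). With 1 array left out the median ran from 0.15 to 0.42 and the adjusted p from 0.000164 to 0.277.

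The replicate numbers gave no clear sign of pairing. Deviations of same-numbered arrays correlated at 0.018, -0.018 and 0.137, and only number 3 matched best with its own. Deviations of the WT arrays were taken from a mean that holds WT array 3, so pairing is not excluded. With the replicate block over the 6 arrays of shared numbers, 0 genes passed, the G1/S list had a median of 0.33 with an adjusted p of 0.187, and 0.290 without the block. The platelet list, at a median of -0.90, passed with the block, adjusted p 0.00220, and without, 0.00596, but not with an estimated correlation, 0.970 and 0.975. WT array 1, whose shift in this list is 2.48, is 1 of the 3 WT arrays here, and without it the median over the other 7 arrays was 0.08. H2-Aa was -0.141 and Gata1 -0.0794 with and without the block. On these 6 arrays the PI3K list median was 0.23, the AKT list 0.18 and Pik3cd 0.27, each opposite in sign to the fit on all 8.

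Values near 0 turned sign elsewhere. Median centring gave 0.0235 for the PI3K list, 0.00782 for the AKT list and 0.0102 for Pik3cd, and quantile normalization 0.0143 for the PI3K list. The stricter filter gave 0.127 for FoxO targets. The median of mast cell, basophil and eosinophil markers lay between -0.690 and -0.0616, the latter without WT arrays 3 and 4, the arrays high in Prg2. Over all 23 settings, no list passed with an estimated correlation, where the smallest adjusted p was 0.613. Array weights gave -0.0825 for Mecom, 0.0476 for Ciita, -0.0633 for H2-Aa, -0.0104 for the GMP list and -0.00981 for the MLL programme, which was -0.0106 without WT array 3 under trend and robust eBayes and -0.0131 without WT arrays 1 and 3. Without WT arrays 1 and 3 the platelet list was 0.111, Eif2s3y 0.148, Pf4 0.33, Treml1 0.224, Mecom -0.303, Bid -0.0379, Igf1r -0.0218, Alas2 0.241 and Slc4a1 0.312. G2/M genes were -0.0200 without WT arrays 3 and 4 and -0.0676 without KO array 1 and WT array 3, where the monocyte list was 0.0145, the glycolysis list -0.00307, Ciita 0.0712, Pik3r5 0.147, the GMP list -0.0354, Hdc -0.252 and Igf1r -0.150. Without WT arrays 3 and 4, Ciita was 0.0874, the GMP list -0.0719 and Igf1r -0.00747. With WT array 3 out, Mecom was -0.121, Ciita 0.0528 and the GMP list -0.0120 with trend and robust eBayes, and Mecom -0.106 and Ciita 0.0968 with quantile normalization. With WT array 3 out, Pik3cb was -0.0260 with trend and robust eBayes, -0.00536 with quantile normalization, -0.0492 also without WT array 1, -0.0244 also without WT array 4 and -0.0176 also without KO array 1.

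With 1 array left out, values ran from -0.391 to 0.0417 for Pik3ca, -0.0260 to 0.501 for Pik3cb, -0.539 to 0.306 for Pik3cd, -1.55 to 0.430 for Uty, -1.0005 to 0.582 for Kdm5d, -0.376 to 0.128 for Eif2s3y, -0.121 to 0.816 for Mecom, -0.210 to 0.0528 for Ciita, -0.177 to 0.195 for H2-Aa, -0.716 to 0.0659 for Treml1, -0.00647 to 0.174 for Gata1 and -0.310 to 0.256 for Slc4a1. List medians ran from -0.164 to 0.0788 for FoxO targets, -0.0106 to 0.205 for the MLL programme, -0.131 to 0.156 for PI3K, -0.106 to 0.107 for AKT, -0.608 to 0.0829 for platelet markers, -0.483 to 0.190 for monocyte markers, -0.0122 to 0.305 for cholesterol genes, -0.480 to 0.0771 for NF-kB genes, -0.0120 to 0.0992 for the GMP list and 0.0393 to 0.180 for G2/M genes.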

Other observations

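Some genes varied between arrays without following the genotype. Prg2, an eosinophil granule gene, was 11.98 in WT array 3 and 12.8 in WT array 4, against a median of 7.81 in the other arrays, and its neighbour in function Prg3, chosen after its values were seen, was 11.6 and 12.4 against 8.07. The erythroid gene Alas2 was 9.97 in WT array 1 and 9.31 in WT array 3, against 5.98 to 7.57 in the others, and Slc4a1, a red cell anion exchanger gene, was 9.51 in WT array 1 and 7.82 in WT array 3. Gata1, an erythroid transcription factor gene and the third tested marker, was 5.96 and 6.13 in these arrays, within the 5.56 to 6.14 of all 8. In WT array 3 the single bright small nucleolar RNA gene was shifted by 2.48 and the T and NK cell list, of 3 members, by 1.31.

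Ribosomal protein genes had a median difference of 0.04 with all arrays and a camera adjusted p of 0.732. Without WT array 3, 47 of 56 were above 0, with a median of 0.07 and a camera adjusted p of 0.0734. Without that array the camera p was 0.416 with an estimated correlation and the fry p 0.269. The list passed in 3 of the 5 settings chosen after seeing the data, and in none of them with an estimated correlation, with adjusted p of 0.714, 0.814 and 0.795.

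Among transcript rows without a symbol, 1149 were bright enough to test, 0 passed and 21 were at an unadjusted p under 0.05 in limma.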
